A study of Mus musculus with 5 samples.

How the data were processed

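In all, 5 mouse RNA-seq libraries of erythroid cells were compared. Per the labels' protocols, the cells were purified with magnetic beads carrying an antibody to CD71, the transferrin receptor encoded by Tfrc, and libraries were made from polyA RNA with an Illumina TruSeq kit. The libraries comprised 1 from the bone marrow of untreated mice (control), 2 from the spleens of mice irradiated on the skin with UVB at 50 mJ/cm2, and 2 from the spleens of mice injected under the skin with B16 melanoma cells (tumor). The labels give no spleen library from untreated mice, so organ and treatment change together in both comparisons with the control. Nothing in the labels says whether libraries of a group came from separate animals. P-values of single genes therefore measure only the spread between these samples, which may be technical.

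The deposited data were 2 tables of 39179 genes with Ensembl identifiers and symbols, 1 for the UVB libraries and 1 for the tumor libraries, each with the control library. The control library held identical values in both tables. Alignment and counting used STAR and HTSeq with genome build mm10, per the submitters' processing notes, and versions, the annotation, the strand setting and any removal of duplicate reads are not given in the sources used here. Values were linear counts per 1000000 reads (CPM) as deposited by the authors, who added 1 read to every gene before scaling each library to 1000000, as the values themselves show. Every value (100%) was a whole multiple of the worth of 1 read within a relative tolerance of 1e-06, so whole reads could be recovered. The authors' deposited log2 fold change columns were the log2 ratio of 1 spleen library to the control library, and were used only to check the scale. Every value column was assigned to a sample.

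The recovered reads in genes numbered 5694656 in the control library, 5003923 and 5921270 in UVB 1 and 2, and 5597803 and 5489850 in tumor 1 and 2. At these depths 1 read was worth 0.168 to 0.198 CPM, which limits the precision of genes of a few CPM, and a deposited value at that level stands for 0 reads. Intervals and floors based on reads cover counting error only, because reads without molecular identifiers are not independent molecules. Exon lengths and positions were taken from GENCODE M21 on GRCm38 (the assembly of mm10), in which 37607 of the 39179 identifiers were found. Reads per gene were compared with exon length, because the most abundant genes did not exceed about 1 read per base of exon.

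Genes with a mean of at least 1 CPM (15006 genes) were tested with limma-trend on log2(CPM + 1), two-sided, in 1 fit of all 5 libraries with 2 residual degrees of freedom. The lone control library was assumed to vary like the spleen groups. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. All fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Where a group had 0 reads, a lower bound on the fold was computed against a floor of 3 reads over the group, and where it had 1 to 3 reads the ratio of reads is given with its exact 95% interval. Gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 36 lists (of 38) that had at least 5 tested members. Of 757 list entries 753 were matched to the tables, with Hbb-b1, Hbb-b2, Ahsp and Emp unmatched. Camera with an estimated correlation called 0 lists in every comparison, against 1 list at unadjusted p under 0.05 in each, so the adjusted p with an estimated correlation is given beside the list calls. With an estimated correlation camera uses only the 2 residual degrees of freedom, so hardly any list could pass. For interferon response between the spleens the estimated correlation of -0.036 lay below the preset one, yet adjusted p went from 5.87e-10 to 0.608. A call lost there is therefore no evidence of correlation within a list. The preset value may in turn make calls too easy where the estimate was far higher (0.98 for B cell markers, 0.95 for macrophage markers and 0.84 for DNA replication genes). List p-values at the preset value compare listed genes with the other genes, so they do not measure how a list varies between libraries.

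Named genes were chosen by a rule fixed beforehand. It takes the 6 largest called changes in each direction with a mean of at least 10 CPM in the higher group and no overlap between libraries, leaving out predicted models, pseudogenes and single antigen receptor segments. It adds up to 2 called members with the smallest p in each called list, and a panel of 15 genes given whatever their values. Other genes are listed by name as members of counted sets or were chosen after their values were seen, as stated beside them.

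The procedure was tested on simulated reads with the depths and means of these libraries, over 15364 genes, with changes planted only in genes of at least 10 CPM. Unlike in these data, the spread was the same in every group and reads per base had no limit. Simulated 4-fold changes against the control were called in 1% (UVB) and 3% (tumor) of 100 genes, and 16-fold changes in 81% and 82%. Between UVB and tumor 56% of 200 4-fold changes and 95.5% of 200 16-fold changes were called. Of the unchanged genes 10 were called in each comparison with the control and 16 between UVB and tumor. Alternatives were other pseudocounts, filters, scalings and variance models, a minimum fold change, the libraries of each comparison alone, the replicate number as a block, each spleen library left out in turn, and edgeR's quasi-likelihood test on the recovered reads. Chosen after seeing the data were a correction for the limit on reads per base, a restriction to genes under 0.1 reads per base, CPM without the added read, crossed replicate numbers, and 8 further gene lists. The result of 1 of these lists and the values of 1 panel gene are not reported here. Overlap of the comparisons that share the control library was set beside 50 simulations of unchanged groups. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.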

Results

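RNA from CD71-selected erythroid cells was sequenced in 5 libraries, 1 from control bone marrow, 2 from the spleens of UVB-irradiated mice and 2 from the spleens of mice bearing B16 melanoma, a transplantable mouse skin tumor. The libraries held between 5003923 and 5921270 reads in genes. Levels below are CPM as deposited, and spleen values are means ± SD of n = 2 libraries, while the control has 1 library and no spread of its own. The tumor libraries differed from each other in more genes (1703 over 2-fold apart, Pearson r = 0.971 across genes) than the UVB libraries did (278 genes, r = 0.989). Across genes, which are not independent replicates, the first principal component took 54.3% of the variance and separated tumor from UVB libraries. On it tumor 1 lay at 79.5, tumor 2 at 28.5, the control at -22.4 and UVB 1 and 2 at -44.7 and -41.0. It thus also held the difference between the tumor libraries. The second component took 33.7% and separated the control from the spleen libraries.

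The erythroid core list stood higher in UVB than in control libraries with 27 of 29 genes above 0 and 0 called (median log2 fold change 0.15, adjusted p = 0.00399, adjusted p = 0.748 with an estimated correlation). It was not called for tumor against control (adjusted p = 0.186) or between the spleens (0.395), although its member Cited4, at 42.2 CPM in the control, 22.9 ± 0.131 in UVB and 105 ± 6.04 in tumor libraries, was called in both (adjusted p = 0.0336 and 0.02). Tfrc, the antigen of the beads, was at 665 CPM in the control, 748 ± 40.4 in UVB and 759 ± 60.4 in tumor libraries. Alas2, the first enzyme of heme synthesis in red cells, was at 317, 360 ± 51.8 and 311 ± 8.18 CPM, and the erythroid regulator Klf1 at 175, 186 ± 2.60 and 203 ± 18.1 CPM. The erythropoietin receptor gene Epor was at 162, 180 ± 1.77 and 168 ± 23.8 CPM. Globin counts were low for red cell precursors, with Hbb-bt at 48.1, 54.6 ± 6.57 and 49.5 ± 2.58 CPM and Hba-a1 at 13.95, 16.5 ± 2.20 and 13.8 ± 2.22 CPM. None of the 6 genes from Tfrc to Hba-a1 was called in any comparison. Reads per base of exon averaged 0.66 for Tfrc, 0.77 for Alas2 and 0.69 for Klf1, close to the highest value of any gene (0.95 to 1.14 per library among genes of at least 200 exon bases), so the differences that could be seen in them were limited. The 4 tested genes of the adult globin list had a median of 0.26 reads per base. The same limit may lower their counts, so low globin counts need not mean low globin expression. The proliferation gene Mki67, chosen after its values were seen, had the highest control level (1420 CPM) at 0.81 reads per base.

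**Figure D1:**
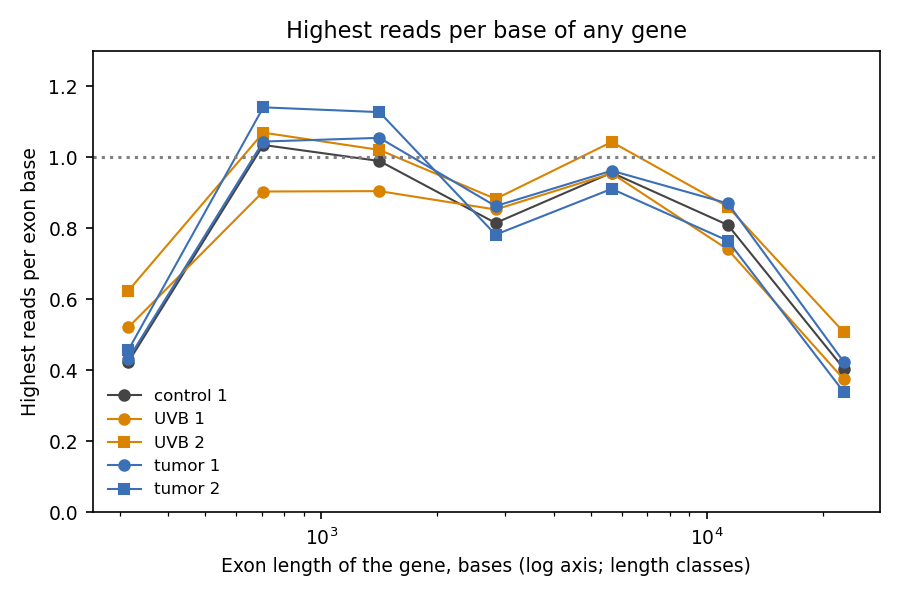
Highest number of reads per base of exon reached by any gene (vertical axis) in classes of exon length (horizontal axis, log scale), with 1 line per library. Between 500 and 16000 bases the highest value stayed between 0.74 and 1.14 in every library. It was lower in genes of 200 to 500 bases (0.42 to 0.62) and of 16000 to 32000 bases (0.34 to 0.51).

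The comparison of UVB spleen with control bone marrow asks how CD71-selected spleen cells of irradiated mice differ from CD71-selected cells of steady-state marrow. Markers of other cells were present too, with B cell markers averaging 6.67 in the control and 7.31 and 7.27 in UVB 1 and 2 on the log2(CPM + 1) scale. Differences therefore cannot be assigned to erythroid cells alone. The largest decreases in the UVB libraries included Col1a1 and Col1a2, the chains of type I collagen, and Dntt and Igll1, which are used by developing lymphocytes. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042 on GRCm38) fell from 275 CPM to 0.717 ± 0.173 (log2 fold change -7.33, SE 0.29, adjusted p = 0.0189). Adamdec1 (ENSMUSG00000022057, chromosome 14, 68563380 to 68582095), which encodes a secreted metalloprotease, rose from 0.698 to 158 ± 23.02 CPM (log2 fold change 6.54, SE 0.38, adjusted p = 0.0189). Over all genes 349 were called, 27 higher and 322 lower. The share of lower genes among those called (92.3%) was much smaller with tumor 1 or tumor 2 left out.

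Of the genes higher in the UVB libraries, the largest changes after Adamdec1 were in Lphn3, an adhesion receptor, Hs3st2, a heparan sulfate sulfotransferase, Ptgis, which encodes prostacyclin synthase, the complement component gene C6 and Rgs1, a regulator of G protein signaling. Control levels rested on 3 reads for Adamdec1 and Hs3st2 and 1 for Lphn3, with read ratios of 299.5 (95% interval 102 to 1454), 129 (43.8 to 625) and 339 (60.6 to 13402.5). Ptgis rose from 0.872 to 66.9 ± 8.53 CPM, C6 from 5.23 to 217 ± 1.51 and Rgs1 from 5.23 to 167 ± 10.1. The largest decreases besides Col1a1 were Col1a2 (227 to 0.717 ± 0.173 CPM), Dntt (215 to 0.885 ± 0.410), Gfra1, a receptor subunit for GDNF (141 to 0.267 ± 0.0971), Igll1 (166 to 0.549 ± 0.0647) and the transcription factor gene Erg (161 to 0.732 ± 0.0863). With 1 read in the UVB libraries, Gfra1 had a read ratio of control to UVB of 1550.2 (95% interval 277 to 61302.4). Adjusted p for these 12 named genes lay between 0.0189 and 0.0329. Calls were lost for Hs3st2 at a mean of at least 5 CPM (adjusted p = 0.0688) or with edgeR (0.069), and for Dntt (0.0559) and Igll1 (0.051) with log2(CPM + 0.25).

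Markers of pro-B and pre-B cells fell in the UVB libraries, with 7 of 10 called lower (Vpreb1, Igll1, Rag2, Dntt, Sox4, Vpreb2 and Erg) and all 10 when adjusted over the list alone (list adjusted p = 1.5e-12, adjusted p = 0.664 with an estimated correlation). Vpreb1 went from 59.5 to 0.450 ± 0.0755 CPM, a read ratio of 217 (95% interval 73.8 to 1059.6). Of 19 neutrophil genes 5 fell, Ly6g, Ctsg, Cebpe, Chi3l3 (Chil3) and Fcnb, or 17 adjusted over the list alone (adjusted p = 1.5e-12, adjusted p = 0.664 with an estimated correlation). Fcnb went from 51.4 to 0.465 ± 0.183 CPM, a read ratio of 188 (95% interval 63.7 to 917). Cebpe went from 30.2 to 0.717 ± 0.173. Stromal markers fell in 7 of 14 genes, or 10 adjusted over the list alone, and included Cxcl12, Pdgfra and Dcn (adjusted p = 2.6e-09, adjusted p = 0.664 with an estimated correlation). Endothelial markers fell in 6 of 16 genes, or 12 adjusted over the list alone, with Emcn at least 23.7-fold and Tek at least 32-fold lower, both with 0 reads in the UVB libraries (adjusted p = 2.3e-05, adjusted p = 0.669 with an estimated correlation). Mast cell, basophil and eosinophil markers had 1 of 5 lower, Epx (11.3 to 0.351 ± 0.216 CPM, a read ratio of 61.4 with a 95% interval of 16.3 to 518). Early erythroid and progenitor genes had 1 of 18 lower, Erg. Both lists had an adjusted p of 0.0489 (adjusted p = 0.669 and 0.748 with an estimated correlation).

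DNA replication genes stood lower as a list (median log2 fold change -0.32, adjusted p = 9.92e-06, adjusted p = 0.748 with an estimated correlation) with 0 of 32 members called. Also without called members, lists stood higher for immediate early and dissociation stress genes (median 0.84, adjusted p = 1.16e-06), type I interferon response (0.34, 0.000263), unfolded protein response (0.17, 0.000392) and dendritic cell markers (0.96, 0.0016). Their adjusted p with an estimated correlation was 0.748, 0.664, 0.664 and 0.748. The same held for terminal maturation (0.17, 0.00309), erythroid core genes (0.15, 0.00399), immunosuppression genes (0.34, 0.00399), MHC class I (0.18, 0.00436), plasma cells (0.36, 0.00477), B cells (0.53, 0.00789), splenic macrophages (0.28, 0.0121) and adhesion genes (0.25, 0.0269). With an estimated correlation the adjusted p of these was 0.664 for terminal maturation and 0.748 for the others. Adjusted over the list alone, 2 immediate early genes and 1 unfolded protein response gene passed. The erythroid core genes had a median of 0.55 reads per base of exon. Of the panel, Kit, the stem cell factor receptor, was at 89.3 CPM in the control and 31.2 ± 9.72 in UVB libraries (adjusted p = 0.137), Cd274, which encodes PD-L1, at 27.6 and 110 ± 0.383 (adjusted p = 0.332). S100a8 was at 55.8 and 11.005 ± 0.141 (adjusted p = 0.165), and the pan-leukocyte gene Ptprc at 332 and 588 ± 60.2 (adjusted p = 0.448). Artn (13.6 and 13.8 ± 1.24 CPM), Arg2 (1.22 and 1.80 ± 0.302), Tgfb1 (202 and 200.6 ± 18.0) and Cd79a (78.5 and 84.4 ± 8.28) were not called either. Without UVB 1 or without UVB 2 no gene was called by limma (0 genes, with 1110 and 1167 at unadjusted p under 0.05). In contrast, 3147 were called without tumor 1 and 3127 without tumor 2. On recovered reads edgeR called 116 genes with all 5 libraries (2085 at unadjusted p under 0.05). Calls of the progenitor and mast cell lists were lost without UVB 2 (adjusted p = 0.072 and 0.0698), without tumor 1 (0.103 and 0.101) or without tumor 2 (0.102 and 0.101). Those of adhesion genes and macrophages were lost without UVB 1 (0.0605 and 0.0918), with a macrophage median of 0.17.

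**Figure D2:**
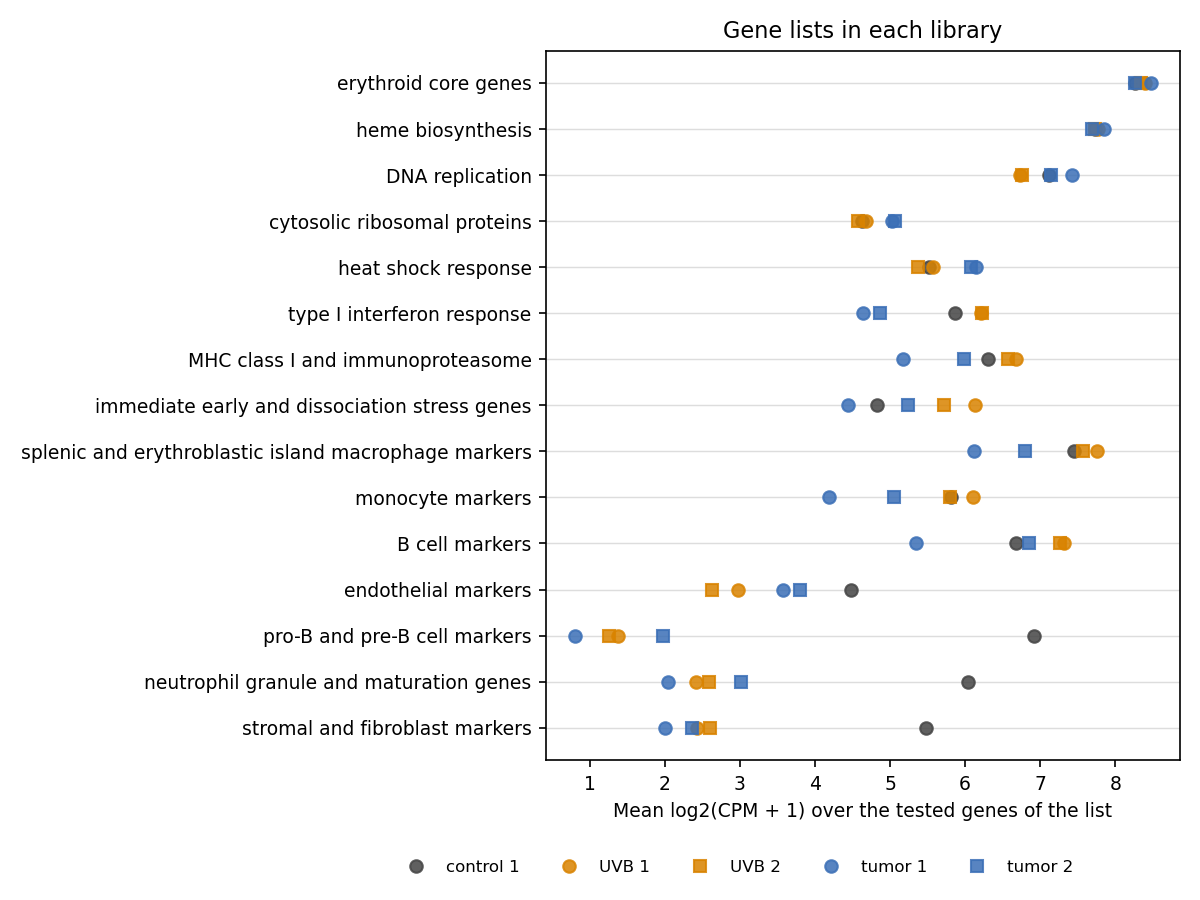
Mean log2(CPM + 1) over the tested genes of 15 gene lists (horizontal axis) in each of the 5 libraries (symbols, color by group). The interferon response list lay at 4.63 and 4.86 in the tumor libraries and at 6.21 and 6.22 in the UVB libraries, and pro-B and pre-B markers lay at 6.92 in the control library alone.

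The comparison of tumor spleen with control bone marrow asks the same of mice carrying melanoma. Podxl (ENSMUSG00000025608, chromosome 6, 31519488 to 31563981), which encodes the sialomucin podocalyxin, rose from 9.59 CPM to 424 ± 11.9 (log2 fold change 5.33, SE 0.25, adjusted p = 0.0171). C2cd4a, at 0 reads in the control, rose to 58.1 ± 3.71 CPM, at least 111-fold higher. Oas2, an antiviral 2'-5' oligoadenylate synthetase, went from 49.5 to 6.62 ± 0.416 CPM and was 1 of 5 called lower among 28 interferon-response genes, as were 2 of 18 macrophage markers. Both lists were called lower (adjusted p = 1.01e-07 and 6.67e-05), but each had an adjusted p = 0.726 with an estimated correlation. Over all genes 569 were called, 180 higher and 389 lower. Without tumor 1 the calls were 1509 higher and 1899 lower, and without tumor 2 they were 1954 and 3491.

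Other large increases were in Adamdec1 (0.698 to 74.8 ± 29.3 CPM, a read ratio of 142 with a 95% interval of 48.5 to 691), Hs6st2, a heparan sulfate sulfotransferase (1.57 to 67.7 ± 2.37), Homer2, a scaffold protein (2.27 to 85.4 ± 24.5) and Ankrd36 (1.40 to 51.2 ± 8.67). The largest decreases were Col1a1 (275 to 0.270 ± 0.1303 CPM, a read ratio of 3070.5 with a 95% interval of 550.3 to 121353), Dntt (215 to 1.08 ± 1.03), Gfra1 (141 to 0.541 ± 0.514) and Mpo, the myeloperoxidase of granulocyte precursors (146.5 to 0.713 ± 0.497). They were followed by Col1a2 (227 to 1.61 ± 0.0220 CPM) and Igll1 (166 to 1.08 ± 1.03). Log2 fold changes of these decreases ran from -7.77 to -6.42 with adjusted p between 0.0171 and 0.0372. With a mean of at least 5 CPM required, Mpo, Ankrd36, Bag3 and Vsig4 were not called (adjusted p = 0.0614, 0.0571, 0.0639 and 0.0692).

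Type I interferon-response genes fell, with 5 of 28 called (Ifit1, Oas2, Xaf1, Ifi44 and Rtp4), or 8 adjusted over the list alone, and a median log2 fold change of -1.15 (adjusted p = 1.01e-07, adjusted p = 0.726 with an estimated correlation). Xaf1 went from 43.3 to 8.42 ± 0.138 CPM. Splenic and erythroblastic island macrophage markers fell in 2 of 18 genes, or 3 adjusted over the list alone (adjusted p = 6.67e-05, adjusted p = 0.726 with an estimated correlation). These were Siglec1 (368 to 26.6 ± 10.2 CPM), a sialic acid receptor of macrophages, and Vsig4 (20.9 to 1.62 ± 1.04). Monocyte markers had 1 of 14 lower, F13a1 (50.8 to 2.78 ± 0.165 CPM), or 6 adjusted over the list alone (adjusted p = 0.00465, adjusted p = 0.726 with an estimated correlation). MHC class I genes stood lower with 0 of 24 called (median -0.41, adjusted p = 0.00093, adjusted p = 0.726 with an estimated correlation). Without tumor 1 the medians were -0.76 for interferon response, -0.21 for MHC class I and -0.31 for macrophages (-0.65 with all libraries, -0.997 without tumor 2). Among leukocyte lists, B cell markers averaged 5.35 in tumor 1 and 6.84 in tumor 2 on the log2(CPM + 1) scale, against 6.67 in the control.

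Of 10 pro-B and pre-B markers 8 fell, and all 10 adjusted over the list alone (adjusted p = 2.3e-10, adjusted p = 0.726 with an estimated correlation). Among them, read ratios of control to tumor were 662 for Vpreb1 (95% interval 118 to 26223) and 269 for Rag2 (91.3 to 1308). Of 19 neutrophil genes 9 fell, including Elane, Prtn3 and Ctsg, or 13 adjusted over the list alone (adjusted p = 6.73e-10, adjusted p = 0.726 with an estimated correlation). Fcnb was at least 191-fold lower, at 0 reads, and Cebpe went from 30.2 to 0.537 ± 0.00735 CPM. Stromal markers fell in 9 of 14 genes, or 13 adjusted over the list alone (adjusted p = 2.3e-10, adjusted p = 0.726 with an estimated correlation). Endothelial markers had 1 of 16 lower, Emcn (6.63 to 0.449 ± 0.133 CPM, a read ratio of 24.0 with a 95% interval of 7.60 to 122), or 3 adjusted over the list alone (adjusted p = 0.00893, adjusted p = 0.726 with an estimated correlation). The neurotrophic list fell through 2 of 5 members, Gfra1 and Ret, which form a GDNF receptor (adjusted p = 0.0136, adjusted p = 0.726 with an estimated correlation). Ret went from 13.3 to 0.270 ± 0.1303 CPM, a read ratio of 146 (95% interval 25.4 to 5844).

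Lists that stood higher were cytosolic ribosomal proteins (median log2 fold change 0.34, 0 of 32 called, adjusted p = 1.26e-05), oxidative phosphorylation (0.23, 0 of 30, 6.67e-05), heat shock response (0.38, 1 of 15, 8.49e-05) and DNA replication (0.21, 0 of 32, 0.018). Their adjusted p with an estimated correlation was 0.726 for the first 3 and 0.853 for DNA replication. Without tumor 2 the DNA replication median was 0.33. Bag3, a co-chaperone, rose from 19.0 to 47.9 ± 2.51 CPM. In lists that were not called, Socs3, a feedback inhibitor of cytokine signaling, rose from 10.8 to 65.1 ± 11.02 CPM and Cited4, Pklr, Osm and Ccl24 were called higher, while Cxcl12, Il33, Tnfsf13b and Epas1 were called lower. Of the panel, Kit was at 89.3 CPM in the control and 86.1 ± 15.6 in tumor libraries (adjusted p = 0.925), Cd274 at 27.6 and 48.5 ± 38.5 (0.699) and S100a8 at 55.8 and 23.9 ± 14.0 (0.23). Ptprc was at 332 and 311 ± 144 CPM (0.834), Artn at 13.6 and 20.4 ± 10.7 (0.618) and Arg2 at 1.22 and 1.44 ± 0.780 (0.90). Tgfb1 was at 202 and 161 ± 18.5 CPM (0.294) and Cd79a at 78.5 and 50.2 ± 28.0 (0.421). Without UVB 1 or UVB 2 limma called 0 genes (2039 and 2035 at unadjusted p under 0.05), against 3408 without tumor 1 and 5445 without tumor 2. With all libraries edgeR called 192 (3405 at unadjusted p under 0.05). List calls lost with 1 library left out were DNA replication, monocytes and endothelium (without tumor 1, adjusted p = 0.623, 0.111 and 0.111, with a DNA replication median of 0.071) and the neurotrophic list (without UVB 1, 0.0846, or tumor 2, 0.0656).

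**Figure D3:**
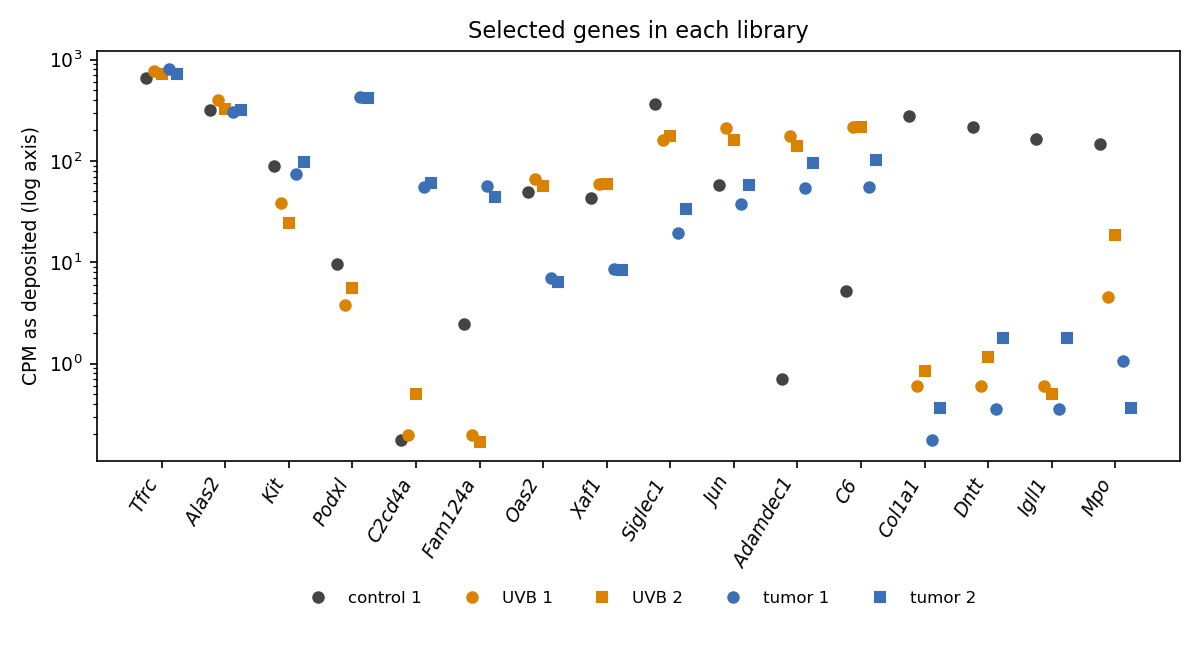
Deposited CPM (vertical axis, log scale) of 16 genes in each of the 5 libraries, with a symbol per library and color by group. Podxl lay at 433 and 416 CPM in the tumor libraries and under 10 CPM in the other 3, while Col1a1 lay at 275 CPM in the control library and under 1 CPM in the spleen libraries.

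Both comparisons share the control library and set spleen against bone marrow, so changes found in both may come from the organ. Of the genes called in each, 264 changed in the same direction in both, 9 higher (among them Adamdec1, C6, Rgs1 and Lphn3) and 255 lower, against 0 in simulated unchanged groups and 0.324 higher and 8.35 lower for independent lists. Thop1, a peptidase gene named after its values were seen, was the 1 gene called in opposite directions, at 63.0 CPM in the control, 27.4 ± 1.57 in UVB and 126 ± 0.556 in tumor libraries. Log2 fold changes had a covariance of 0.42 across genes, against 0.079 in simulated unchanged groups, a difference of 0.34, and a Pearson r of 0.56 against 0.67. The signs matched for 48.02% of genes, against 73.2% in the simulations. The simulated counts leave out the effects and the independent lists leave out the shared control, so an excess over either is not by itself a shared effect. The single control library cannot be split, so part of it may come from there, and 0 genes overlapped without UVB 1 or without UVB 2.

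The comparison of UVB with tumor spleen sets the 2 treatments against each other within 1 organ. Of 28 interferon-response genes 15 were called higher in the UVB libraries (list adjusted p = 5.87e-10, adjusted p = 0.608 with an estimated correlation), with Oas2 (ENSMUSG00000032690, chromosome 5, 120730333 to 120749853) at 61.2 ± 7.09 CPM against 6.62 ± 0.416 (log2 fold change 3.02, SE 0.18, adjusted p = 0.02). Podxl was higher in the tumor libraries, at 424 ± 11.9 against 4.65 ± 1.25 CPM (log2 fold change UVB minus tumor -6.25, SE 0.20, adjusted p = 0.02). Kit was higher in the tumor libraries too, at 86.1 ± 15.6 against 31.2 ± 9.72 CPM (adjusted p = 0.0365, adjusted p = 0.0574 without a variance trend). Over all genes 2557 were called, 705 higher in UVB and 1852 higher in tumor libraries. The majority turned around without tumor 2 (4086 higher in UVB, 3814 in tumor) and was slight without tumor 1 (2726 in UVB, 3011 in tumor).

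The largest differences toward UVB were in Fosb, an immediate early transcription factor (89.0 ± 65.4 against 5.77 ± 5.14 CPM), Sned1 (98.9 ± 9.09 against 10.96 ± 5.47) and Icos, a T cell costimulatory receptor (26.2 ± 4.38 against 2.43 ± 1.93). They were followed by Oas2, Ifit3 (27.7 ± 0.980 against 3.42 ± 2.58 CPM) and Mybpc1 (21.7 ± 4.99 against 2.34 ± 1.55). The 6 genes had log2 fold changes of 2.83 to 3.76 and adjusted p of 0.02 to 0.0479. Toward tumor they were in Podxl, C2cd4a (58.1 ± 3.71 against 0.351 ± 0.216 CPM, a read ratio of 319 with a 95% interval of 87.9 to 2638) and Fam124a (at 0 reads in UVB, at least 185-fold higher in tumor). They were followed by Gmpr, a guanosine monophosphate reductase (66.9 ± 13.02 against 1.14 ± 0.766 CPM), Ano1, a calcium-activated chloride channel (33.6 ± 0.427 against 0.267 ± 0.0971, a read ratio of 368 with a 95% interval of 65.6 to 14555) and Arhgdig (48.9 ± 12.6 against 1.32 ± 0.744).

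Of 28 interferon-response genes 15 were higher in UVB and 0 lower, or 24 adjusted over the list alone, with a median log2 fold change of 1.38 (adjusted p = 5.87e-10, adjusted p = 0.608 with an estimated correlation). Xaf1 was at 59.3 ± 0.564 against 8.42 ± 0.138 CPM. MHC class I and immunoproteasome genes had 2 of 24 higher in UVB, the GTPase gene Igtp (66.8 ± 2.79 against 35.8 ± 3.82 CPM) and H2-T23 (118 ± 4.07 against 76.7 ± 1.81), with the list at adjusted p = 2.14e-06 (adjusted p = 0.741 with an estimated correlation). Immunosuppression and checkpoint genes had 4 of 25 higher in UVB, Lgals1 (20.0 ± 1.46 against 8.15 ± 0.745 CPM), 4632428N05Rik, which is Vsir (325 ± 4.18 against 189 ± 5.397), Vsig4 and Havcr2, or 3 adjusted over the list alone (adjusted p = 0.00016, adjusted p = 0.741 with an estimated correlation). Immediate early and dissociation stress genes had 3 of 20 higher, Fosb, Jun (187 ± 35.7 against 48.0 ± 14.5 CPM) and Egr1 (77.9 ± 0.837 against 23.2 ± 11.7), or 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00043, adjusted p = 0.741 with an estimated correlation). The list averaged 6.13 and 5.72 in UVB 1 and 2 and 4.44 and 5.24 in tumor 1 and 2 on the log2(CPM + 1) scale. A response to treatment cannot be told apart from one to cell isolation here.

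Splenic macrophage markers were higher in UVB in 7 of 18 genes, or in all 18 adjusted over the list alone, including Siglec1 (169 ± 10.4 against 26.6 ± 10.2 CPM) and the hemoglobin scavenger receptor gene Cd163 (362 ± 67.6 against 130 ± 22.9), with a median log2 fold change of 1.16 (adjusted p = 3.66e-07, adjusted p = 0.741 with an estimated correlation). Monocyte markers had 2 of 14 higher, Fcgr1 (84.8 ± 11.7 against 25.1 ± 6.93 CPM) and F13a1 (8.24 ± 0.442 against 2.78 ± 0.165), or 12 adjusted over the list alone (adjusted p = 3.64e-05, adjusted p = 0.741 with an estimated correlation). T cell markers had 1 of 12 higher, Cd4 (60.6 ± 13.3 against 15.3 ± 8.57 CPM), or 3 adjusted over the list alone (adjusted p = 0.0039, adjusted p = 0.741 with an estimated correlation). Plasma cell markers had 1 of 12 higher, Prdm1 (45.2 ± 3.66 against 13.5 ± 5.50 CPM, list adjusted p = 0.0294, adjusted p = 0.744 with an estimated correlation). B cell markers stood higher with 0 of 18 called (median 1.20, adjusted p = 0.000417, adjusted p = 0.744 with an estimated correlation), as did NK cell markers with 0 of 5 (median 0.91, adjusted p = 0.0445, adjusted p = 0.741 with an estimated correlation). Dendritic cell markers stood higher (median 0.89, adjusted p = 0.0187, adjusted p = 0.741 with an estimated correlation) although Zbtb46 was called lower, and adhesion genes stood higher (median 0.89, adjusted p = 0.021, adjusted p = 0.741 with an estimated correlation) with Cd36 higher (299 ± 4.91 against 195.5 ± 27.1 CPM) and Itga5 lower. Tumor 1 stood apart, with B cell markers lower by 1.53 than in tumor 2. Without tumor 1 the medians were 0.43 for B cells, 0.43 for adhesion genes, 0.73 for macrophages, 0.58 for NK cells and 0.51 for dendritic cells, and without tumor 2 they were 1.97 for B cells and 1.39 for adhesion genes.

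In the other direction, DNA replication genes were higher in tumor in 13 of 32 members, or 24 adjusted over the list alone, with a median log2 fold change UVB minus tumor of -0.51 (adjusted p = 5.34e-07, adjusted p = 0.741 with an estimated correlation). Mcm10 was at 229 ± 29.0 in tumor against 117 ± 5.21 CPM in UVB and Gins2 at 53.05 ± 8.52 against 22.1 ± 1.06. Oxidative phosphorylation genes were higher in 8 of 30, including Ndufs1 (176 ± 1.26 against 108 ± 5.59 CPM) and Uqcrc1 (165 ± 2.56 against 112 ± 1.29), with a median of -0.38 (adjusted p = 8.32e-06, adjusted p = 0.741 with an estimated correlation, 11 adjusted over the list alone). Heat shock genes were higher in 7 of 15, including the mitochondrial chaperone gene Hspd1 (89.2 ± 2.23 against 46.9 ± 4.11 CPM) and Hsph1 (253 ± 28.2 against 107 ± 25.5), with a median of -0.57 (adjusted p = 0.000417, adjusted p = 0.741 with an estimated correlation, 9 adjusted over the list alone). Of 32 ribosomal protein genes 4 were higher, Rpl27 (22.4 ± 0.559 against 10.7 ± 0.238 CPM), Rps24 (19.8 ± 1.12 against 8.62 ± 1.27), Rps19 and Rps20, with a median of -0.31 (adjusted p = 0.00045, adjusted p = 0.741 with an estimated correlation), but 0 passed when adjusted over the list alone. Endothelial markers were higher in 7 of 16, including Egfl7 (28.5 ± 0.389 against 2.78 ± 0.841 CPM) and Plvap (35.6 ± 5.68 against 7.28 ± 1.76), and lower in 1, Stab2 (list adjusted p = 0.0203, adjusted p = 0.741 with an estimated correlation). Terminal maturation genes stood higher in UVB with 2 of 22 called, Ube2h (228 ± 2.59 against 139 ± 10.3 CPM) and Atg4a (73.5 ± 1.99 against 46.7 ± 3.67), at an adjusted p of 0.00129 (adjusted p = 0.741 with an estimated correlation).

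Lists that were not called still held called genes. Of 23 stress erythropoiesis genes 6 were higher in tumor (Kit, Ptch1, Smo, Stat5a, Socs3 and Podxl) and 2 in UVB, Bmpr1a and Kitl (list adjusted p = 0.336). Of 23 glycolysis genes 8 were higher in tumor, including Pklr and Ldha (list adjusted p = 0.309). Among 18 early erythroid and progenitor genes 4 were higher in tumor (Kit, Gata2, Myb and Myc) and 1 in UVB, Runx1 (camera, list adjusted p = 0.75). Of the remaining panel, Cd274 was at 110 ± 0.383 in UVB and 48.5 ± 38.5 CPM in tumor libraries (adjusted p = 0.147) and Ptprc at 588 ± 60.2 and 311 ± 144 (0.104). Tgfb1 was at 200.6 ± 18.0 and 161 ± 18.5 CPM (0.144) and Cd79a at 84.4 ± 8.28 and 50.2 ± 28.0 (0.185). S100a8 was at 11.005 ± 0.141 and 23.9 ± 14.0 CPM (0.177), Artn at 13.8 ± 1.24 and 20.4 ± 10.7 (0.446) and Arg2 at 1.80 ± 0.302 and 1.44 ± 0.780 (0.589). Limma called 0 genes without UVB 1 or UVB 2 (2424 and 2681 at unadjusted p under 0.05), 5737 without tumor 1 and 7900 without tumor 2. With all libraries edgeR called 2008 (5942 at unadjusted p under 0.05). List calls lost with 1 library left out were adhesion genes, plasma, NK and dendritic cells (without UVB 1, adjusted p = 0.0529, 0.153, 0.0582 and 0.0872), plasma, T and NK cells (without tumor 1, 0.106, 0.0511 and 0.172) and endothelium (without tumor 2, 0.115).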

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

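The results below differ between UVB and tumor spleen by the test of that difference itself. Except for the contrasts, all tests of explanations in this part were chosen after the patterns were seen. Fold changes against the control, called or not, differed between the treatments in the following genes, with log2 fold changes UVB minus tumor of 1.17 for Lphn3, 2.51 for Ptgis, 1.51 for C6, 1.40 for Rgs1, 3.02 for Oas2, 2.68 for Xaf1, 1.29 for F13a1, 2.68 for Siglec1 and 1.66 for Vsig4, all higher in UVB. Higher in tumor were Podxl (-6.25), C2cd4a (-5.46), Hs6st2 (-4.14), Homer2 (-3.73), Ankrd36 (-2.30), Kit (-1.46), Tek (-1.17) and Bag3 (-0.79). Kit, a panel gene, was not called against the control in either group. Median log2 fold changes of called lists were 1.38 for interferon response, 1.26 for monocytes, 1.20 for B cells, 1.19 for immunosuppression genes, 1.16 for macrophages, 1.16 for immediate early genes, 1.15 for T cells, 0.91 for NK cells, 0.89 for dendritic cells, 0.89 for adhesion genes, 0.75 for MHC class I, 0.50 for plasma cells and 0.30 for terminal maturation. With an estimated correlation none of the 18 called lists was called by limma camera (0 lists, with 1 of all 36 at unadjusted p under 0.05), and their adjusted p ran from 0.608 to 0.744. In the other direction the medians were -1.16 for endothelial markers, -0.57 for heat shock, -0.51 for DNA replication, -0.38 for oxidative phosphorylation and -0.31 for ribosomal proteins. Without tumor 1 the medians were 0.75 for monocytes, 0.43 for B cells, 0.64 for immunosuppression genes, 0.73 for macrophages, 0.65 for immediate early genes, 0.62 for T cells, 0.58 for NK cells, 0.51 for dendritic cells, 0.43 for adhesion genes and 0.23 for plasma cells. Without tumor 2 they were 1.97 for B cells, 1.87 for immediate early genes, 1.39 for adhesion genes and 0.82 for plasma cells, and T cells had 0.68 without UVB 1 and plasma cells 0.76 without UVB 2.

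Reads per gene leveled off near 1 per base of exon in all 5 libraries. In genes near this level, poor recovery of short transcripts would leave reads in proportion to depth. Yet in 42 genes with exons under 2000 bases and at least 0.5 reads per base UVB 2 held 1.09 times the reads of UVB 1 (95% bootstrap interval 1.07 to 1.11), against 1.17 (1.17 to 1.18) in 5764 genes under 0.1 reads per base. Short genes with fewer reads per base lay outside this test. Among genes of 200 to 500 exon bases the highest value was 0.42 to 0.62 per library, so poor recovery of the shortest transcripts stays open. The ratio over all 107 genes with at least 0.5 reads per base was also 1.09 (1.08 to 1.11), as keeping 1 read per start position predicts. Any other limit on reads per position could give the same ratio. So could a lower share of abundant transcripts in UVB 2, since these ratios rest on 1 pair of libraries. Under a limit on reads per position, similar values of erythroid genes across libraries may hide differences in their abundance.

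Interferon-response genes were lower in the tumor than in the UVB libraries. Under 3 other scalings the list's lowest median was 1.38, while the median of all genes lay between -0.021 and 0.027. The list thus stood above the bulk of genes under each of them. As these scalings moved the genes so little, they could hardly have removed such a difference. Fewer leukocytes could not be judged as the whole cause. Between the tumor libraries the list's median differed by -0.0011 (tumor 2 minus tumor 1, interval -0.28 to 0.53), although its mean rose from 4.63 to 4.86 on the log2(CPM + 1) scale. Macrophage markers differed by 0.59 (0.37 to 0.80), a gap of -0.59 (-0.95 to -0.049), and B cell markers by 1.53 (1.33 to 1.68). The gap was chosen, and the rule for reading it changed, after values were seen, so no verdict is drawn. The intervals are over genes in 1 pair of libraries, and that of the 15 called genes alone (-0.25 to 0.74) includes the macrophage value. Fewer leukocytes stay open as part or all of the difference. A difference between the treatments in interferon signaling of the erythroid cells stays open and was not tested.

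Podxl, C2cd4a, Hs6st2, Homer2 and Ankrd36 were far higher in the tumor libraries than in the control and UVB libraries. B16 melanoma cells as the source are argued against by the pigment cell genes Mlana, Pmel, Tyr, Tyrp1 and Dct, which together reached at most 1.64 reads per 1000000 in a tumor library (interval 0.75 to 3.11) and 4.39 in the control (2.84 to 6.48), although Mc1r, another member of the melanocyte list, was called higher in tumor (2.33 ± 0.285 CPM) than in UVB (0.282 ± 0.162, adjusted p = 0.0301, list adjusted p = 0.399) and stood at 0.698 in the control. Over the control, where the 5 genes had log2 fold changes of 4.43 to 5.65, endothelial markers did not rise as a list. Their median was -0.86 (interval -1.15 to -0.19), or -0.74 in tumor 2 alone (-1.18 to 0.12). In UVB libraries they stood lower than the control too (median -2.27). The control is from another organ, so a lower median against it cannot exclude endothelial cells. For the difference from UVB endothelial cells stay open too, since their markers were higher in tumor (median UVB minus tumor -1.16, interval -1.84 to -0.0063). That median was smaller in size than the difference of any of the 5 genes. A response of splenic erythroid cells to the tumor, a type of cell outside the lists, or another cause may underlie the pattern. None of these was tested.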

How the results depend on the processing

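Alternatives not planned before the data were examined were the correction for reads per base, the restriction to genes under 0.1 reads per base, CPM without the added read and the crossed block. Under the alternatives run, no called gene chosen by the rule or the panel and no called list of the 36 tested changed direction, while other genes named in the text were not rerun under them. The lists added later, also chosen after the data were examined, were rerun only with each spleen library left out. The causes of the changes below were not tested except where fewer libraries or genes entered.

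For UVB against control (349 genes called), log2(CPM + 0.25) gave 101, log2(CPM + 5) 542, no filter 541, a mean CPM of at least 5 gave 67, its own libraries alone 3077 and edgeR 116, and leaving out 1 library gave 0 to 3147. For tumor against control (569), the same settings gave 232, 874, 70 (at least 5 CPM), 0 (own libraries, with 2150 genes at unadjusted p under 0.05) and 192 (edgeR), quantile normalization gave 929, and leaving out 1 library gave 0 to 5445. For UVB against tumor (2557), no filter gave 1556, quantile normalization 3939, no variance trend 1411, a minimum log2 fold change of 1 gave 1272, genes under 0.1 reads per base 1307, and leaving out 1 library 0 to 7900. Without a UVB library the spread came from the tumor pair alone, which differed more. The overlap of 264 genes was 73 with log2(CPM + 0.25), 45 at a mean of at least 5 CPM and 0 to 1263 with 1 library left out.

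Quantile normalization moved the share of lower calls from 92.3% to 78.1% and from 68.4% to 59.4% against the control and from 72.4% to 59.3% between spleens, with a median of all genes of 0.11 for tumor against control. With its own libraries alone UVB against control had 55.5% lower (1368 higher, 1709 lower). Without a variance trend the share was 82.3% for tumor against control, and with a minimum log2 fold change of 1 it was 59.6% for UVB against tumor.

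Of 18 called genes chosen by the rule or panel for UVB against control, log2(CPM + 0.25) lost 5 (Dntt, Igll1, Epx, Emcn and Tek) and edgeR 4 (Hs3st2, Epx, Emcn and Tek). Of 24 for tumor against control, log2(CPM + 0.25) lost 5 (Mpo, Bag3, Ret, Vsig4 and Emcn), edgeR 5 (Ankrd36, Bag3, Ret, Vsig4 and Emcn), no variance trend 3 (Mpo, Bag3 and Vsig4), CPM without the added read 2 (Bag3 and Vsig4) and no filter 1 (Vsig4). Of 39 between spleens, no variance trend lost 12 (Fosb, Ube2h, Atg4a, Hsph1, Ndufs1, Uqcrc1, H2-T23, Cd36, Prdm1, Cd4, Egr1 and Kit), a minimum log2 fold change of 1 lost 11, and no filter 8 (Fosb, Atg4a, Rpl27, Rps24, Cd36, Cd4, F13a1 and Egr1). CPM without the added read lost 3 there (Fosb, Cd4 and Egr1), genes under 0.1 reads per base 2 (Fosb and Cd4), and log2(CPM + 0.25) and robust eBayes Fosb and edgeR Uqcrc1.

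Called lists numbered 19, 13 and 18, and 0 in each comparison with an estimated correlation. Among genes under 0.1 reads per base 10 lists were called for UVB against control and 9 for UVB against tumor, where 26 lists could be tested. Of the called lists that could be tested, 3 of 13 lost their call for UVB against control, terminal maturation (adjusted p = 0.513), adhesion genes (0.632) and MHC class I (0.109). For tumor against control 1 of 10 did, MHC class I (0.156). Between UVB and tumor 6 of 15 did, terminal maturation (0.445), adhesion genes (0.483), plasma cells (0.221), NK cells (0.0729), dendritic cells (0.192) and immediate early genes (0.202). The progenitor and mast cell lists of UVB against control lost their calls with log2(CPM + 0.25) (0.058 each) and with the correction for reads per base (0.0559 each). NK cell markers lost their call with median-of-ratios scaling (adjusted p = 0.0542, and up to 0.741 under the other alternatives).

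The labels do not tie replicate numbers across groups. With the number as a block limma called 0 genes between UVB and tumor (5428 at unadjusted p under 0.05), and 17 of 33 lists. Deviations of same-numbered libraries correlated at -0.11, and the crossed pairing as a block called 3071 genes. Depths of 5003923 to 5921270 reads and the limit on reads per base restrict what can be seen in low genes and in the most abundant ones.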

Other observations

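The gene lists of this part and the test of cytokine-STAT5 targets were chosen after the main results were seen. Genes of ribosome biogenesis, the assembly of ribosomes in the nucleolus, were higher in tumor than in UVB libraries in 28 of 30 members, with a median log2 fold change UVB minus tumor of -1.04 (limma camera, adjusted p = 1.7e-15, adjusted p = 0.143 with an estimated correlation). Against the control 13 of 30 rose in tumor libraries (adjusted p = 1.8e-18, adjusted p = 0.12 with an estimated correlation) while in UVB libraries the list stood lower with 0 of 30 called (median -0.17, adjusted p = 0.00779, adjusted p = 0.433 with an estimated correlation). Rrp12 was at 154 ± 8.44 CPM in tumor, 43.1 ± 2.11 in UVB and 52.0 in the control library, and nucleolin (Ncl) at 602 ± 11.5, 343 ± 13.6 and 429 CPM. Nucleotide and one-carbon synthesis genes followed, with 18 of 25 higher in tumor than in UVB (adjusted p = 2.45e-11, adjusted p = 0.133 with an estimated correlation). Against the control 5 of 25 rose in tumor libraries (adjusted p = 4.42e-08, adjusted p = 0.12 with an estimated correlation), and the list stood lower in UVB libraries with 1 of 25 called (median -0.38, adjusted p = 7.69e-07, adjusted p = 0.228 with an estimated correlation). Cad, which starts pyrimidine synthesis, was at 491 ± 0.129 CPM in tumor, 145 ± 11.3 in UVB and 224 in the control library, and Impdh1 was lower than the control in both spleen groups.

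MHC class II genes stood higher in UVB than in tumor libraries with 0 of 10 called (median 1.18, adjusted p = 0.00166, adjusted p = 0.53 with an estimated correlation), as did marginal zone and follicular B cell genes with 0 of 17 called (median 1.45, adjusted p = 0.00018, adjusted p = 0.53 with an estimated correlation). The B cell markers moved with them (median 1.20) and were lower by 1.53 in tumor 1 than in tumor 2, and the medians of these 2 lists were 0.55 each without tumor 1 and 1.81 and 2.19 without tumor 2. Against the control both stood higher in UVB libraries with 0 called (medians 1.06 and 1.27, adjusted p = 1.13e-05 and 1.41e-07, adjusted p = 0.433 each with an estimated correlation). They were not called for tumor against control (medians 0.14 and 0.25, adjusted p = 0.647 and 0.441), where without tumor 1 both were called higher (5e-06 and 3.32e-07) and without tumor 2 MHC class II was called lower (0.0254). Of 7 Hedgehog pathway genes Smo and Ptch1 were higher in tumor (list adjusted p = 0.215), with Smo at 51.5 ± 3.11 against 5.003 ± 1.62 CPM. Red cell membrane genes were not called between the spleens (median 0.11, adjusted p = 0.117, or a median of 0.19 without tumor 1), at a median of 0.36 reads per base of exon. Against the control they stood higher in UVB libraries with 0 called (median 0.13, adjusted p = 0.00408, adjusted p = 0.47 with an estimated correlation). In tumor libraries they were not called against the control (median 0.041, adjusted p = 0.647).

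A hypothesis written before its test, but after the main results were seen, was that a program of cell growth is higher in tumor than in UVB libraries. The ribosome biogenesis list passed with the preset correlation but not with an estimated one (adjusted p = 0.143). With 2 residual degrees of freedom the second test could hardly be passed, so the hypothesis may hold but stays open. Cell cycle and mitosis genes, a list fixed beforehand, were not called between the spleens (median -0.18, 1 of 30 higher in tumor, adjusted p = 0.0828). DNA replication genes were called (median -0.51). Macrophage, monocyte and B cell markers were higher in UVB (medians 1.16, 1.26 and 1.20). The difference therefore cannot be assigned to erythroid cells. A related hypothesis was that cytokine signaling through STAT5 is higher in tumor libraries. Between the spleens its target list stood higher in tumor with 4 of 17 called, Socs3, Osm, Myc and Cdk6 (adjusted p = 0.0249). It did not pass with an estimated correlation (adjusted p = 0.381), a test too weak here to decide. Against the control the list was not called in tumor (median 0.29, adjusted p = 0.129) or UVB libraries (median 0.17, adjusted p = 0.716). Cish was at 162 ± 49.6 CPM in tumor and 51.6 ± 25.0 in UVB libraries (adjusted p = 0.0569).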
